A study of Penaeus merguiensis with 6 samples.

How the data were processed

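Gene expression was measured by RNA sequencing in the hepatopancreas, the digestive and storage gland of crustaceans, of the banana shrimp Penaeus (Fenneropenaeus) merguiensis. Per the labels, 3 libraries came from shrimp held for 72 hours in water with 0.5 mg/L cadmium and 3 from control shrimp, which the design text places at 0 mg/L. Total RNA was extracted with TRIzol and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The labels number the libraries 1 to 3 within each group. They do not say which tank or how many animals each library came from, so p-values measure the spread between these samples, which may be partly technical.

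The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 57303 assembled genes, with 1 column per library, and per the file headers the column names are the sample titles. The values carry 2 decimals. The IDs have the form that the Trinity de novo assembler gives its genes. The assembler, quantifier, their versions and any filter are not given in the sources used here, and no genome build is named. No gene name or sequence accompanies the IDs here (0 of 57303 were paired with one), and no reference was used. The 31 gene lists fixed before the data were examined (metal binding, heat shock proteins, antioxidant enzymes, immunity, markers of other cell types and others) could therefore be matched to no gene, and their set tests were not run. Of the genes in the table, 6420 were at 0 in every library.

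The FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), in 1 model over the 6 libraries with no covariate. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries entered the test, which left 19862 genes. The threshold was a two-sided Benjamini-Hochberg adjusted p of 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low genes. No fold is given for a gene listed at 0 in a whole group. Measures per library were compared with an exact two-sided permutation test, whose smallest p with 3 libraries against 3 is 0.1, and Benjamini-Hochberg adjusted over the 15 measures compared. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

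The rule for genes named in the text was fixed before the data were examined. For IDs without gene names it takes the 2 largest fitted increases and the 2 largest fitted decreases past the threshold with all libraries of one group above all of the other, and the 5 genes with the highest mean FPKM. Other genes are described without their IDs.

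The depth of the libraries is not recorded in the table, so it was examined through the low values. In genes above 0 in at most 4 libraries, ratios to control 1 were taken, and only those within a fixed cut around 1 were kept. Within most ranges of level the kept ratios lay close together, as whole fragments would give. At steps of 0.3 to 0.5 FPKM, 1 fragment relative to control 1 was worth 0.917 in control 2 and 0.979 in control 3. It was worth 0.979 in cadmium 1, 0.939 in cadmium 2 and 0.909 in cadmium 3. By these ratios the libraries were of similar depth, but the cut bounds them, so a large difference in depth was not tested. The ratio changed with the size of the step, and the steps were therefore calibrated within 13 ranges of step size. A gene was called a few-fragment gene when all its values were whole multiples of one calibrated step, within 1.5% plus rounding, with at most 20 fragments over the 6 libraries. These fragment numbers are the smallest whole numbers that fit. Of the 19862 tested genes, 3340 (16.8%) had such a solution. After multiplying each value by a random factor, 180 (0.906%) did. That rate is over all tested genes. It was not computed for genes at 0 in a whole group, where fewer values have to fit and a solution by chance is easier. In those 3340 genes the median worth of 1 fragment was 1.43 FPKM, and the 5th and 95th percentiles were 0.42 and 8.11 FPKM, so a single fragment can pass an FPKM of 1. On simulated data with known fragment numbers, 98.1% of 2577 genes were solved with the true numbers up to a common factor. The simulated values were built from the same calibrated steps, with 1 step per gene and little noise. Interquartile ranges of the real ratios at steps of 2.5 to 3.5 FPKM were 0.0041 (control 3) to 0.0206 (cadmium 2). The 98.1% is therefore not the share of few-fragment genes found in the real data. Steps above 30 FPKM were not calibrated. A tolerance of 3% was also tried, at which 3378 genes had a solution, and 2.67% of genes did after random factors. This classification was added after the data were seen.

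The limma step was tested on simulated data made from the means and spreads of the 19862 genes of the cadmium against control comparison, with 200 changed genes in each of 5 draws. It recovered 4% of genes changed 2-fold and 42.4% of those changed 4-fold. It recovered 68% of those changed 8-fold and 79.2% of those changed 16-fold, with 5.6 false calls per draw on average. The simulated changes were on the log2(FPKM + 1) scale, and the noise was normal, without values held at 0 or whole-fragment steps. The 5.6 therefore does not give the error rate for all-or-none genes. In the real data, regroupings of the 6 libraries that mix the groups called 17 to 37 genes. Fixed alternatives were another pseudocount (0.1), no filter, a mean FPKM of at least 5, upper-quartile, quantile and median-of-ratios scaling, limma without the trend, a 2-fold minimum, the replicate number as a block, and leaving out each library. A test without the few-fragment genes was added after the data were seen. The groups share replicate numbers, but the same-numbered libraries deviated together only weakly. Their correlations of deviations from the group means were 0.0276, 0.0144 and 0.0369, against -0.0418 to 0.0168 for libraries of other numbers. The labels do not say that the numbers pair the libraries, so they were not treated as pairs in the main model.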

Results

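Hepatopancreas libraries of the banana shrimp were compared, 3 from animals exposed to 0.5 mg/L cadmium for 72 hours and 3 from controls. The design text gives this as the median lethal concentration at 72 hours, from a preliminary trial. The deposited FPKM summed to between 1702598 (cadmium 1) and 2003399 (control 2) per library, and between 33155 (control 1) and 37231 (control 3) of the 57303 assembled genes were above 0. Numbers of fragments are not recorded in the table. The assembled genes carry no gene names here, so they are described by ID, level and pattern.

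A few assembled genes made up much of the hepatopancreas FPKM. The 5 genes with the highest mean FPKM held 33.3% ± 6.74 (SD, n = 3) of the summed FPKM in the controls and 25.6% ± 2.5 (SD, n = 3) with cadmium. The groups overlapped, with control 2 at 26.8% and cadmium 2 at 28.3% (exact two-sided permutation test, p = 0.2, adjusted 0.6). The gene at the top, TR431_c25_g2, stood at 227776 ± 40596 FPKM (SD, n = 3) in controls and 169351 ± 18778 FPKM (SD, n = 3) with cadmium. TR431_c25_g3, from the same assembly component, stood at 163434 ± 16983 and 128722 ± 13213 FPKM. TR15793_c0_g1, TR15379_c0_g3 and TR15793_c0_g2 followed, at 88989 ± 10160, 88369 ± 21390 and 36960 ± 9058 FPKM in controls against 69856 ± 8549, 56731 ± 7441 and 25295 ± 3177 FPKM with cadmium. In 4 of these 5 genes every cadmium library lay below every control library as deposited, in 5 after upper-quartile or median-of-ratios scaling and in 0 after quantile normalization. None passed the test, with limma adjusted p between 0.641 (TR15379_c0_g3) and 0.824 (TR431_c25_g3).

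The libraries of the cadmium group resembled each other more than those of the control group did. Across the 19862 tested genes, Pearson correlations of log2(FPKM + 1) were 0.886 to 0.904 between cadmium libraries, 0.851 to 0.875 between control libraries and 0.848 to 0.891 between groups. These correlations are across genes, which are not independent replicates. The first principal component, with 27.1% of the variance, placed the 3 cadmium libraries on one side and the 3 controls on the other (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows, adjusted 0.5). The second, with 23.1%, set control 3 apart from the other 5 libraries.

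The comparison of cadmium with control asks which hepatopancreas genes change at a lethal cadmium concentration. Among genes with a mean FPKM of at least 1000, the change past the threshold was 1 rise. The gene had the eighth highest mean FPKM. It went from 2786 ± 315 FPKM (SD, n = 3) in controls to 40704 ± 15444 FPKM (SD, n = 3) with cadmium. Its control libraries read 2878, 2435 and 3046 FPKM and its cadmium libraries 25354, 56240 and 40517 FPKM. The fitted log2 fold change was 3.80 ± 0.35 (SE), or 13.9-fold, with an adjusted p of 0.0193 (limma). It was the only gene past the threshold among the 220 with a mean FPKM of at least 1000, and it lost its call when any library but cadmium 1 was left out (adjusted p 0.0678 to 0.125), with log2 fold changes of 3.53 to 3.87. The call also ended with no filter on low values (limma adjusted p = 0.136). Among the 688 genes with a mean of 100 to 1000 FPKM, 3 passed the threshold, all higher with cadmium.

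Over all genes, 71 of 19862 passed the threshold, 58 higher and 13 lower with cadmium. With one library left out at a time the count fell to between 10 (without cadmium 3) and 43 (without cadmium 1). Most of the 71 were all-or-none: 43 of the 58 higher genes were listed at 0 in every control, and all 13 lower genes were listed at 0 in every cadmium library. The 15 other higher genes were above 0 in both groups. Of these, 11 were above 0 in all 6 libraries, with fitted increases between 3.15-fold and 24.1-fold, and 4 were at 0 in at least 1 control. With one library left out at a time, 8 of the 11 passed in none of the 6 fits, and none of the 15 passed in all 6. No gene above 0 in both groups fell past the threshold.

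The 2 largest fitted increases belonged to genes listed at 0 in all 3 controls. TR4760_c1_g1 read 343.65, 278.5 and 370.86 FPKM in the cadmium libraries (limma adjusted p = 9.02e-05) and TR16630_c0_g1 read 135.03, 484.41 and 426.49 FPKM (adjusted p = 0.00491). The 2 largest fitted decreases belonged to genes listed at 0 in all 3 cadmium libraries. TR5036_c0_g1 read 91.27, 22.3 and 45.82 FPKM in the controls (adjusted p = 0.0175), which corresponds to 4, 1 and 2 fragments in the smallest whole-number solution. It lost its call without control 3 (adjusted p = 0.0741) and without cadmium 1, 2 or 3 (0.0904, 0.0862 and 0.117; limma). TR12630_c0_g1 read 21.31, 21.35 and 43.68 FPKM (adjusted p = 0.00606). Without cadmium 3, TR16630_c0_g1 and TR12630_c0_g1 lost their calls too (adjusted p = 0.0569 and 0.0587).

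**Figure D1:**
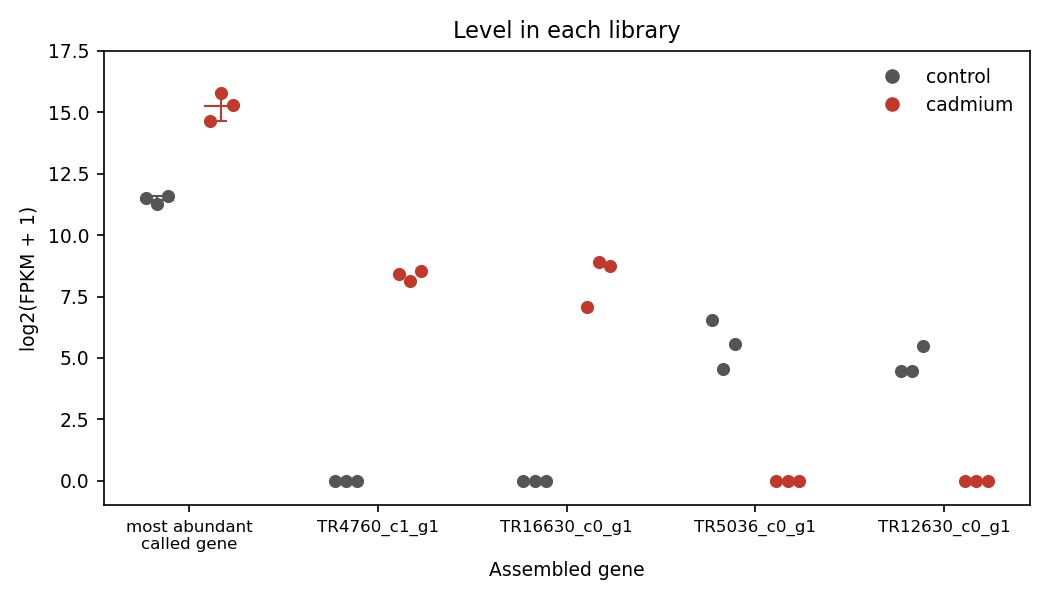
Level of 5 assembled genes as log2(FPKM + 1) in each control (grey) and cadmium (red) library. Points are libraries, and for the most abundant gene past the threshold the horizontal mark and bars give the mean and SD (n = 3). The other 4 genes are at 0 in all 3 libraries of one group.

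Most of the genes past the threshold had values that a few fragments could give. Of the 71 genes, 46 were few-fragment genes, whose values were whole multiples of the worth of 1 fragment with at most 20 fragments over the 6 libraries. They were 34 of the 58 higher and 12 of the 13 lower. In 21 of the 71, 15 higher and 6 lower, the values corresponded to 1 fragment in each library of one group and 0 in the other. The remaining 25 genes were 24 higher and 1 lower with cadmium, and 15 of them were above 0 in both groups. The lower one, TR12630_c0_g1, was outside the tolerance of 1.5%. At a tolerance of 3% all 13 lower genes were few-fragment genes, and 23 higher genes were left. When the few-fragment genes were left out before the test, an alternative added after the data were seen, 17 of 16522 genes passed. They were 16 higher and 1 lower (limma, Benjamini-Hochberg adjustment). Of the 17, 7 were above 0 in both groups, and 16 were among the 25. The most abundant gene past the threshold remained among the 17 (limma adjusted p = 0.0285). With 1 library left out as well, 3 to 21 genes passed. That gene then passed only without cadmium 1, with limma adjusted p of 0.066 to 0.225 in the other fits.

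**Figure D2:**
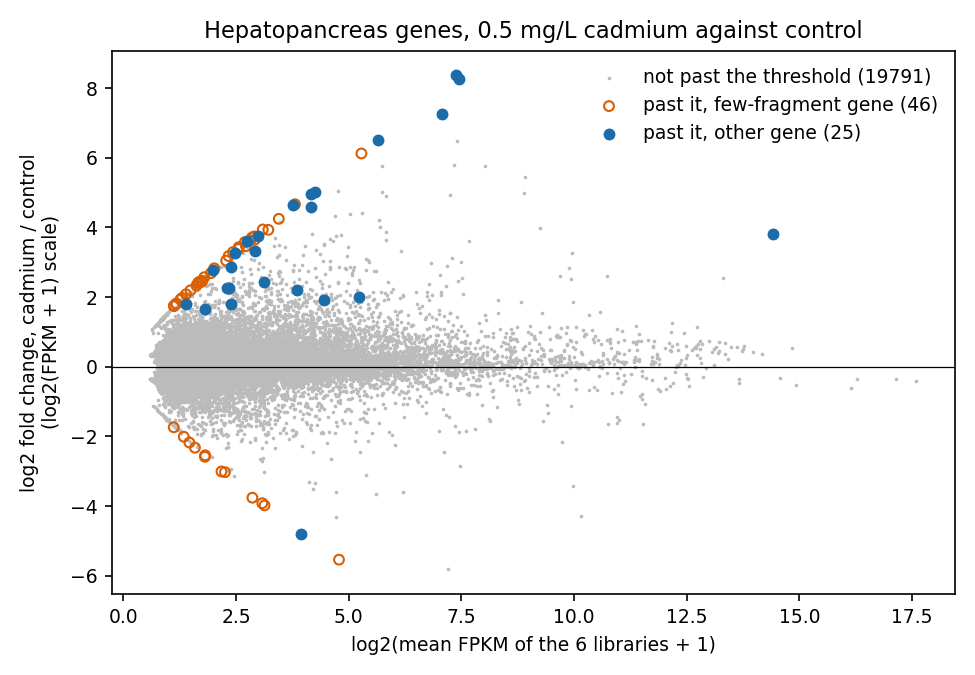
Fitted log2 fold change of cadmium over control (vertical axis, log2(FPKM + 1) scale) against log2 of the mean FPKM of the 6 libraries + 1 (horizontal axis) for the 19862 tested genes. Grey points did not pass the threshold, and the 46 open orange circles (few-fragment genes) and 25 blue points (other genes) did. The single blue point far to the right is the gene that rose 13.9-fold.

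All-or-none genes were more numerous in the cadmium group whether or not they passed the threshold. Among the tested genes, 137 were above 0 in all 3 cadmium libraries and at 0 in all 3 controls, against 65 for the reverse. The 18 trios that mix the groups gave 46 to 109 such genes each. Without the few-fragment genes, 18 genes were on with cadmium alone and 2 in controls alone, against 1 to 8 in the mixed trios. With 20 trios no smaller share than 1 in 20 can be reached, and trios share libraries, so no p-value is attached.

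**Figure D3:**
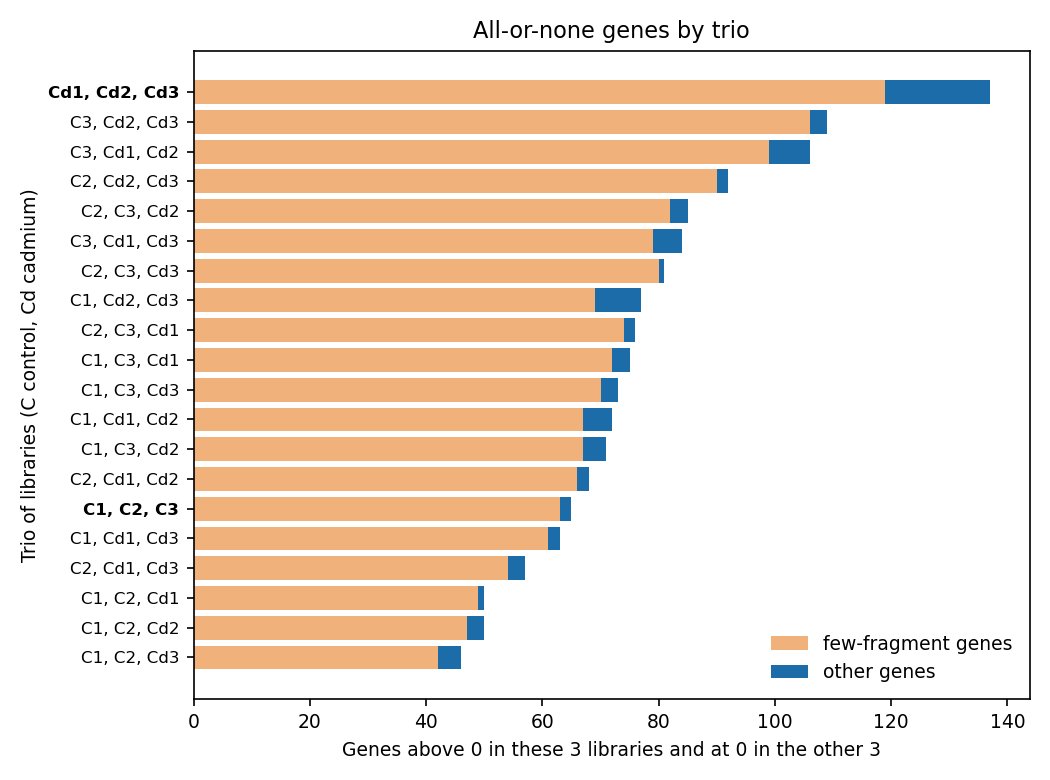
Number of tested genes above 0 in a given trio of libraries and at 0 in the other 3 (horizontal axis), for all 20 trios (vertical axis; C control, Cd cadmium, the real groups in bold). Orange marks few-fragment genes and blue the others. The cadmium trio has 137 genes, 18 of them blue, and the control trio 65, 2 of them blue.

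At an unadjusted p under 0.05, 1893 genes differed, the genes past the threshold included, where chance alone gives 993 and the 9 other splits of the libraries gave 679 to 1191 (limma). With cadmium 1417 of them were higher and 476 lower in the FPKM as deposited. That balance depended on the scaling, since the median log2 fold change of all tested genes was 0.11 as deposited and -0.04 after upper-quartile scaling, where 926 genes were higher and 987 lower. Quantile normalization gave 933 higher and 965 lower, with a median of -0.04, while median-of-ratios scaling left more genes higher (1107) than lower (804), with a median of 0.01. Groups did not overlap in 15.1% of the tested genes as deposited and in 16.2% after upper-quartile scaling, where chance gives 10%.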

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

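The 71 genes past the threshold (58 higher, 13 lower) depended on the fit. The counts were 27 (20 and 7) with no filter on low values, 14 (12 and 2) with a mean FPKM of at least 5, 134 (105 and 29) for limma without the trend, 17 (16 and 1) without few-fragment genes, and 14 (14 and 0, with 344 lower at an unadjusted p under 0.05 in limma) without those at a 3% tolerance, both of which also test fewer genes. What caused these counts to differ was not tested. Pseudocount 0.1, the 3 scalings and the 2-fold minimum gave 58 to 71 genes. The 2-fold minimum could remove no call, since the smallest fitted log2 change among the 71 was 1.66. It is counted among the 15 alternatives below all the same. Of the 71, 52 passed with pseudocount 0.1 and 55 to 58 with the scalings. With one library left out the counts ran from 10 to 43 (8 to 33 higher, 2 to 10 lower), the lowest without cadmium 3, and 9 of the 71 genes, 6 of them few-fragment genes, passed in all 6 such fits and 29 in none. With a library left out and no few-fragment genes they ran from 3 to 21 (3 to 18 higher, 0 to 3 lower). With the replicate number as a block, 1 gene passed, TR4760_c1_g1, and 0 were lower (1777 genes at an unadjusted p under 0.05 in limma, 420 of them lower). The numbers are not known to pair the libraries, though 5 of 6 correlated best with their own number, weakly. The block leaves only 2 residual degrees of freedom. Of the 4 named all-or-none genes, 4 passed in the main test, 1 with the block, 2 without few-fragment genes at a 3% tolerance (which leaves the other 2 untested), and 1 to 4 with a library left out. TR4760_c1_g1 passed in all 15 alternatives set beforehand (adjusted p 2.89e-05 to 0.0276), and TR16630_c0_g1 and TR12630_c0_g1 in 13 each. TR5036_c0_g1 passed in 10 (up to 0.184), and the most abundant gene past the threshold in 8 (0.014 to 0.255). The log2 fold change of the last ran from 3.53 to 4.10. The other 4 are at 0 in a whole group, which fixes their direction. Of the 5 genes with the highest mean FPKM, quantile normalization, which fixes the values of the top ranks, turned TR15793_c0_g1 from -0.35 to 0.075 (log2), took TR15379_c0_g3 from -0.62 to -0.075 and took TR431_c25_g2 and TR431_c25_g3 to 0. Low genes are limited by the worth of 1 fragment (median 1.43 FPKM in few-fragment genes, picked for having few fragments). Only 4% of simulated 2-fold changes were recovered.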

Other observations

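The tests in this part were chosen after the results were seen.

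Abundant genes also differed between libraries of one group. The genes with the sixth, the ninth and the tenth highest mean FPKM stood at 11510, 7493 and 6261 FPKM in control 1, against ranges of 24539 to 41666, 15744 to 24897 and 11719 to 24970 FPKM in the other 5 libraries. In the same library the 5 most abundant genes held 40.3% of the summed FPKM, against 23.4% to 32.8% in the others.

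The calls may come in part from sampling of a few fragments. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: the real split called 71 genes and the highest of the others 37, and 1 split of 10, the real one, reached that count. Among few-fragment genes the real split called 46 and the others 14 to 35, so splits that mix the groups also call many such genes, as sampling of few fragments would give. The real count lies above all of the others, and sampling need not account for all 46. Among the other genes the real split called 25 and the others at most 5, and at a tolerance of 3% the numbers were 23 and at most 5. As far as 10 splits can show, calls of such genes were rarer in splits that mix the groups. This cannot decide on sampling, because these genes were set apart by having no few-fragment solution. A real difference between the groups would also widen the spread within mixed splits and lower their counts. Only 16 of the 25 still passed when the few-fragment genes were left out before the test. Single genes among them stay open as well: steps above 30 FPKM were not calibrated, and TR12630_c0_g1 counts as a few-fragment gene at 3%. Without few-fragment genes the real split called 17, the highest of the others 5, and again 1 split of 10 reached the real count, so the splits cannot settle it.

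Control 3 held 2742 genes at an FPKM of at least 1 that were at 0 in every other library, against 1005 to 1662 in each of the others, and 638 against 254 to 370 at an FPKM of at least 10. Slightly greater depth is argued against, since 1 fragment was worth 0.979 times its value in control 1. In cadmium 3, where it was lowest, it was worth 0.909. Much greater depth was not tested, because ratios far from 1 were not used. The 10 most abundant genes held 38.7% of the summed FPKM in control 3 and 31.7% in control 2, so their FPKM share was not lowest in control 3. Shares of summed FPKM are not shares of fragments. Whether the most abundant genes took fewer fragments there therefore stays open. RNA from another tissue or organism may contribute. The genes listed only in control 3, at an FPKM of at least 1, held 1.55% of its summed FPKM. Without names or sequences, such RNA cannot be told apart from a difference between animals. Without control 3 the main comparison gave 32 genes.

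The FPKM worth of 1 fragment differed between groups in genes with large steps. At steps of 20 to 30 FPKM it was 0.844 ± 0.031 (SD, n = 3) times that of control 1 in cadmium libraries and 0.994 ± 0.014 (SD, n = 3) in controls (exact two-sided permutation test, p = 0.1, the smallest possible, adjusted 0.5), a ratio of 0.849, against 0.976 at steps of 0.3 to 0.5 FPKM. The values at the large steps rest on 4 to 8 genes per library other than control 1. A fixed cut on the ratios used lay just below those of cadmium 2 and cadmium 3. A difference in depth alone is argued against, because it would shift all steps by one factor and the ratios differed by 0.127. A length correction that uses each library's fragment sizes is a candidate explanation of the ratio of 0.849, and stays open because fragment sizes are not in the table. Whatever its source, it cannot be told apart from the groups, and equal fragment numbers in such genes read as lower FPKM with cadmium.

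The hypothesis that genes of one assembly component change together under cadmium was tested on 1639 pairs from 1180 components without few-fragment genes. The correlation of their log2 fold changes was 0.127 (one-sided permutation test of 1000 shuffles, p = 0.001, the smallest they can give), but the other splits of the libraries gave 0.0997 to 0.231, so it is not specific to cadmium.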
